A study of Rattus norvegicus with 16 samples.

How the data were processed

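RNA was measured in the spleens of 16 Sprague Dawley rats, 8 in each of groups M and C, with 1 library per offspring as the labels describe them. Per the labels' protocols, total RNA was made into strand-specific libraries after removal of ribosomal RNA. Trimmomatic, HISAT2, StringTie, Bowtie2 and the rat genome build Rnor_6.0 were used, per the submitters' processing notes, which give these names without versions, roles or order. The tool that counted the reads and its strand setting are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, are uncertain in these counts.

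The authors deposited whole-number counts per gene symbol for the 16 libraries in a table of 22601 genes, of which 19230 had a count in any library. A second deposited table, named as FPKM, held the same bytes as the counts, and was left out because its values are counts. Among its symbols, 27 had been turned into calendar dates, which is a known effect of spreadsheet software on the septin and March gene names, and 2 names occurred more than once. These were kept as separate genes under their altered names. A table of rat genes on the assembly GRCr8 was used only for names and for which genes lie next to each other, since it is another build than the authors'.

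Groups were taken from the treatment label of each library. Replicates were numbered in the order of their records, which pairs no libraries. Each library was counted as a sample of its own because the labels describe separate offspring. No 2 libraries of 1 group held the same library counted again: the smallest reduced chi-square over genes with a mean count of at least 50 was 10.8 among 56 pairs. That value does not show that the libraries came from independent animals. The first number in a library's title was shared by several libraries within a group and by none across groups. What it stands for is not given in the sources used here. The titles of M3 and M8 share their second number too and differ only in a final letter. These 2 libraries were kept as separate animals, and the Y-linked gene Eif2s3y was at 0.571 CPM in M3 and 82.8 CPM in M8. Litter, sex and sequencing batch are not given either. The labels describe the animals as separate offspring. If some were littermates, the p-values take them as more independent than they were.

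Depth was taken as the total count of each library, from 14479140 to 32473324 with a median of 18774038. For genes with few counts, the sum over the 8 libraries of a group was given without an interval. A floor of 3 counts was used as the level that a count of 0 allows, about 0.0198 library-size-scaled counts (CPM) in C and 0.0194 CPM in M. These floors cover counting error only.

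Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust estimation, TMM scaling factors and edgeR's default expression filter, which left 14251 genes. The model held the group alone. Fold changes are log2 values of M minus C, so a positive value is higher in M, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values use the TMM-scaled library sizes, and log2 CPM values were computed with a prior count of 2. The biological coefficient of variation common to all genes was 26.6%.

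Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between members, adjusted over 37 lists. Camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean per library over all 12870 divisions of the libraries into 8 and 8 stood beside it. Of 39 lists, 2 were not tested: the mitochondrially encoded list had 0 members past the filter, fewer than the 3 required, and the sex-linked list, with 2, served only as a check. A Th17 minus Treg score was the difference between the mean z-scores of log2 CPM over the tested members of both lists. It was compared by the exact two-sided permutation test of the difference between group means.

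The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names the genes of largest change with an adjusted p under 0.05, a mean of at least 1 CPM and a gene symbol other than a locus identifier. Where fewer than 10 genes pass, as here, it names the 10 such genes with the smallest p in each direction, as values only. It also names up to 4 members of each list past the threshold over all genes, of which there were none, and a fixed set of Th17, Treg, cytokine, PI3K/Akt and NF-κB genes, of which a few, and a measure built on them, are not reported here. Other genes named in the text were chosen after their values were seen.

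The edgeR procedure was tested on simulated counts for this comparison with the means, library sizes and dispersions of the 14251 genes, changed genes being drawn among those with a mean of at least 1 CPM. It recovered 10 of 50 genes changed 1.25-fold (20%), 33 of 50 changed 1.5-fold (66%), 43 of 50 changed 2-fold (86%) and 50 of 50 changed 4-fold (100%), and called 7 unchanged genes. With no gene changed it called 0. A simulated shift of the Treg list by 0.3 on the log2 scale gave an adjusted p of 0.000395 in camera. Each gene was drawn independently, so simulated genes did not vary together between libraries. In the data the members of the Treg list had an estimated correlation of 0.0966. The simulation therefore does not show how edgeR or camera perform where genes vary together.

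The alternatives were other scaling factors, no filter and a stricter filter, DESeq2 1.42.0, limma voom with quality weights, edgeR without robust estimation, the first title number as a random block or with its libraries summed, 1 surrogate variable from sva 3.50.0, the erythroid list mean as a covariate, totals without haemoglobin and immunoglobulin genes, other prior counts, and each library left out in turn. Alternatives on FPKM values were not run, because the second table holds counts. Xist as a covariate was not run, because it is not among the genes of the counts table, and Eif2s3y, a Y-linked gene, took its place after the data were seen. Also added after the data were seen were the erythroid mean together with Eif2s3y, the exact permutation test of list means, and a fit without M4, M7 and M8, which hold many counts of 45S-like genes.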

Results

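The study asked whether chronic stress of pregnant rats alters the balance of Th17 and Treg cells in the offspring and whether the PI3K/Akt/NF-κB pathway takes part. Th17 cells are helper T cells that make interleukin 17, and Treg cells are T cells that restrain immune responses. Gene expression was measured by RNA sequencing of whole spleen from 16 Sprague Dawley offspring. Group M came from dams exposed for 21 days to a changing series of mild stressors, among them crowding, damp bedding, shaking, a tilted cage, restraint, fasting and a swim in ice-cold water. Group C came from the comparison dams. Each group held 8 libraries from offspring weaned at day 21. Total counts per library were 18982235 ± 1623372 in C and 19373979 ± 5655379 in M (SD, n = 8 each). The deepest library was M8 with 32473324 counts, and the shallowest was M6 with 14479140. The Y-linked gene Eif2s3y was above 10 CPM in 4 of 8 libraries of each group (C5 to C8 and M5 to M8).

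The first comparison concerned the Th17 and Treg programmes, and neither differed detectably between the groups in the genes that could be tested. The cytokines that define Th17 cells were almost absent from whole spleen at this depth. Il17a had 0 counts over the 8 libraries of C and 1 count over the 8 libraries of M. Il17f had 4 counts in C and 2 in M, and Il22 had 2 counts in C and 0 in M. A difference in these 3 genes could not be detected, since the sums lie near the floor of 3 counts among 151857883 counts in C and 154991829 in M. Il21, a cytokine of Th17 and follicular helper T cells, had 20 counts in C and 29 in M.

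Foxp3, the lineage factor of Treg cells, was measured well above that floor. Its level was 7.09 ± 1.72 CPM in C and 8.40 ± 2.28 CPM in M (SD, n = 8), a log2 fold change of 0.25 with a 95% interval from -0.13 to 0.62 and an edgeR adjusted p of 0.827. Il2ra, the high-affinity interleukin 2 receptor chain of Treg and activated T cells, had a log2 fold change of 0.03 (SE 0.15). Ctla4, an inhibitory receptor, had 0.20 (SE 0.18). The anti-inflammatory cytokine genes Il10 and Tgfb1 had values of -0.15 (SE 0.34) and 0.08 (SE 0.07), and the gene of the interleukin 23 receptor, Il23r, had 0.28 (SE 0.35). The edgeR adjusted p of these 5 genes lay between 0.839 and 0.967.

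Of the Treg list 21 members were tested, 15 higher and 6 lower in M, with a median log2 fold change of 0.06. Of the Th17 list 14 members were tested, 8 higher and 6 lower, with a median of 0.01. The filter removed Il17a, Il17f, Il21, Il22, Csf2 and Ccl20 from the Th17 list. What remained included genes as high as Stat3, at 268 CPM in C. The Th17 list test and the score below therefore do not measure these cytokine genes and say little about Th17 cells themselves. No member of the Treg or Th17 list passed the threshold over all genes or adjusted over the list alone. Camera with the preset correlation gave an adjusted p of 0.0809 for Treg and 0.509 for Th17, and with an estimated correlation the adjusted p was 0.804 and 0.825. The Treg list passed the threshold when C7, M2 or M5 was left out, with an adjusted p of 0.0145, 0.0254 and 0.0441. The Th17 list took the opposite direction with the erythroid list mean as a covariate (adjusted p = 0.898).

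The Th17 minus Treg score was 0.0569 ± 0.420 in C and -0.0569 ± 0.251 in M (SD, n = 8 each), a difference of -0.11 that was smaller than the spread between libraries (exact two-sided permutation p = 0.520). The size of this difference rested on single libraries: it was -0.06 without C1, -0.01 without C4, -0.17 without C5, -0.20 without C7, -0.18 without M3 and -0.07 without M8, with exact permutation p between 0.222 and 0.926 when any 1 library was left out.

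**Figure D1:**
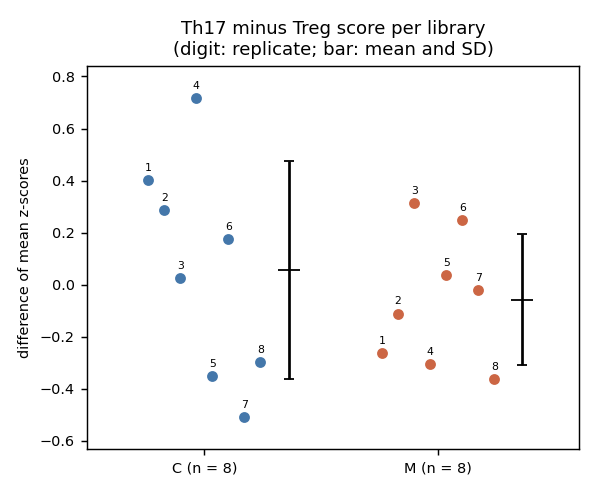
Th17 minus Treg score (difference of mean z-scores) in each library of C and M, with replicate numbers at the points and the mean and SD as bars. The groups overlap, with a difference between M and C of -0.11.

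The second comparison concerned transcripts of the PI3K/Akt/NF-κB pathway, and none of its genes differed detectably between the groups. Transcript levels do not measure the activity of the proteins, so whether the pathway takes part stays undecided here. Pik3ca, a catalytic subunit of PI3K, had a log2 fold change of -0.08 (SE 0.04), and Pik3cd, the catalytic subunit common in leukocytes, had 0.14 (SE 0.08). Pik3cb and the regulatory subunit gene Pik3r1 had values of -0.05 (SE 0.11) and 0.05 (SE 0.05). The kinase genes Akt1 and Akt2 had values of -0.05 (SE 0.07) and -0.08 (SE 0.18). For Akt1, present at 178 ± 15.7 CPM in C and 171 ± 17.1 CPM in M (SD, n = 8 each), the 95% interval ran from -0.19 to 0.09. The genes of the NF-κB subunits had log2 fold changes of 0.07 for Nfkb1, 0.14 for Nfkb2, 0.05 for Rela and 0.07 for Relb, with SE from 0.05 to 0.09. Nfkbia, which encodes an inhibitor of NF-κB and is itself induced by it, had 0.11 (SE 0.10). The kinases that release NF-κB had 0.06 (SE 0.04) for Ikbkb and -0.12 (SE 0.06) for Chuk. Among its targets, Il6 had -0.30 (SE 0.23) and Il1b had -0.14 (SE 0.09), and Tnf had 32 counts in C and 26 in M, too few to be tested. The edgeR adjusted p was 0.741 or more for each tested gene of this paragraph.

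**Figure D2:**
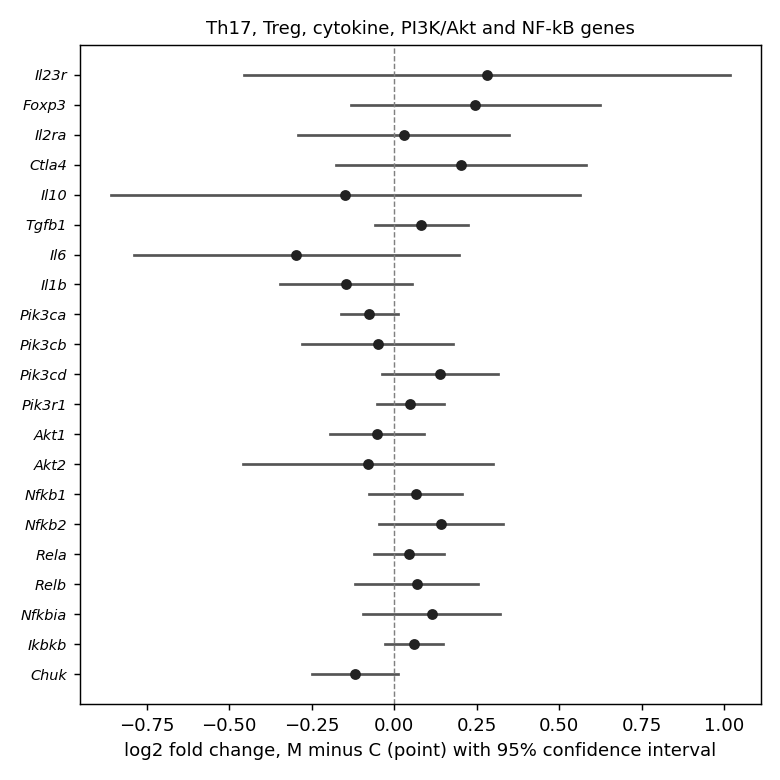
Log2 fold change of M minus C (points) with 95% confidence intervals (lines) from edgeR for tested genes of the fixed set. Every interval drawn includes 0, among them Foxp3 with -0.13 to 0.62 and Akt1 with -0.19 to 0.09.

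All 35 members of the PI3K/Akt list were tested, 22 higher and 13 lower in M, with a median log2 fold change of 0.03 and a camera adjusted p of 0.137 (0.655 with an estimated correlation). The NF-κB target list had 17 of 25 tested members higher and 8 lower, with a camera adjusted p of 0.291 (0.825 with an estimated correlation). The list of NF-κB components stood higher in M by camera with the preset correlation: 21 of its 28 members were higher and 7 lower, with a median of 0.05 and an adjusted p of 0.0281. With an estimated correlation its adjusted p was 0.804, and with the erythroid list mean as a covariate it was 0.222. The mean log2 CPM of this list fell as that of the erythroid list rose across libraries (described further on). No member of the 3 lists passed the threshold over all genes or adjusted over the list alone. The call on NF-κB components was lost when any of C3, C4, C5, C8, M3, M6, M7 or M8 was left out, with adjusted p of 0.0784, 0.0775, 0.236, 0.0947, 0.0917, 0.103, 0.0982 and 0.0625, and PI3K/Akt passed the threshold with library totals as the only scaling (0.0442).

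The third comparison covered all genes, and edgeR found 0 of 14251 genes that differed between M and C. At an unadjusted p under 0.05 there were 1003 genes, 538 higher and 465 lower in M, against 713 that chance would give. There were 361 genes in a limma voom fit with the first title number as a random block, and 562 in edgeR with counts summed over that number, which leaves 7 summed samples. Without M5 that number was 1602, and without M4, M7 and M8 together it was 452. DESeq2 called 34 genes, 22 higher and 12 lower in M, and 18 of them were among the 20 genes named next. Without M4, M7 and M8, DESeq2 called 7 genes, of which 4 were also called with all libraries.

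The genes with the smallest p among those lower in M included a pair of larger differences. Asic1, an acid-sensing ion channel, was at 5.16 ± 2.08 CPM in C and 1.56 ± 0.570 CPM in M (SD, n = 8 each), a log2 fold change of -1.70 (SE 0.30) with an edgeR adjusted p of 0.162. Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, was at 20.1 ± 6.75 CPM in C and 9.58 ± 1.46 CPM in M, a log2 fold change of -1.07 (SE 0.19) with the same adjusted p of 0.162. All 8 libraries of M lay below the median of C for both genes, while C2 lay within the range of M for Asic1 and C2 and C8 did for Gpd1. Without C2, edgeR called both genes, Asic1 with an adjusted p of 0.00416 and Gpd1 with 0.0314, and without C8 it called Gpd1 alone (0.0487). LOC103694306, which had the smallest p of all genes, was among the genes called without M5 or M6. Without M5 edgeR called LOC103694306 and LOC679149 (both 0.0174), and without M6 it called Asb15 and LOC103694306 (both 0.00872). These 3 genes were chosen after their values were seen.

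Pak2, a kinase of the cytoskeleton, and Nptx1, a neuronal pentraxin, had log2 fold changes of -1.81 (SE 0.39) and -1.52 (SE 0.32). Smaller values with narrow errors were seen for Emc2, part of a complex that inserts membrane proteins (-0.26, SE 0.05), Rpl22l1, a paralogue of a ribosomal protein (-0.36, SE 0.07), and Cd48, a surface ligand on leukocytes (-0.27, SE 0.06). The others among the 10 genes with the smallest p in this direction were Thnsl1, Fam171b and Mpp5, with log2 fold changes of -0.39, -0.46 and -0.22. In the other direction, Sidt1, a transmembrane protein that binds RNA and cholesterol, was at 29.5 ± 2.39 CPM in C and 38.2 ± 4.81 CPM in M (SD, n = 8 each), with a log2 fold change of 0.37 (SE 0.08) and an edgeR adjusted p of 0.206. Aoc3, the amine oxidase VAP-1 of blood vessels, had 0.40 (SE 0.08), and Fer1l6 had 1.11 (SE 0.25). The remaining genes higher in M were Adamtsl4 (0.36), Zfp330 (0.26), Hap1 (0.64), Zfp579 (0.38), Myrf (0.38), Cdc42bpg (0.21) and Apc2 (0.37). The edgeR adjusted p of these 20 genes lay between 0.162 and 0.413. The 2 groups did not overlap for 4 genes, Emc2, Rpl22l1, Sidt1 and LOC102552170, where chance gives 0.0155% of genes, or 2.21 genes here.

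**Figure D3:**
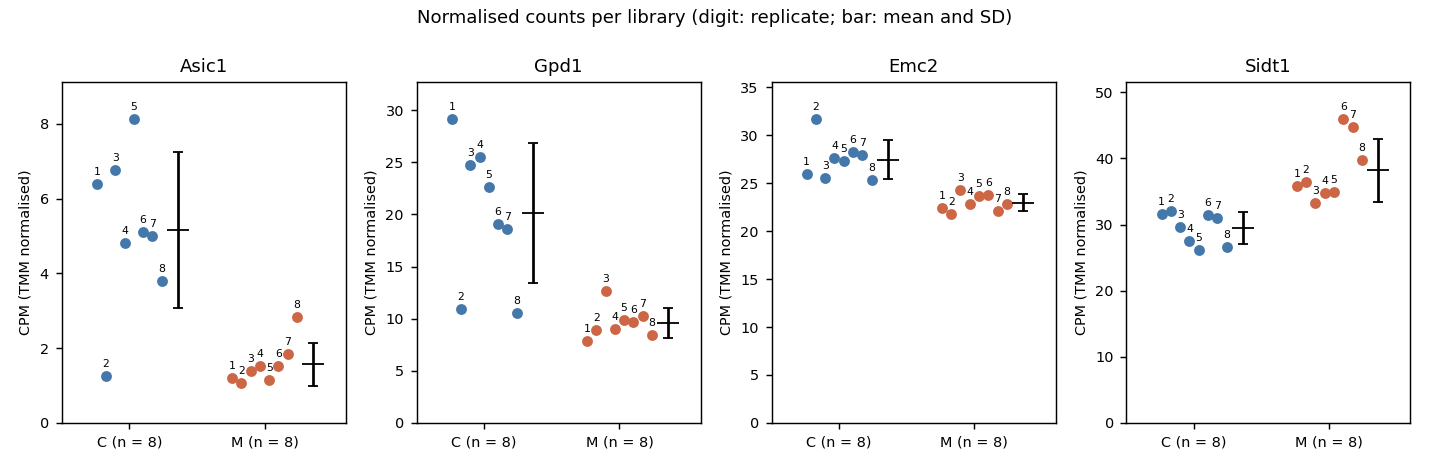
TMM-normalised counts (CPM) of Asic1, Gpd1, Emc2 and Sidt1 in each library of C and M, with replicate numbers at the points and the mean and SD as bars. C2 lies among the M libraries for Asic1, and C2 and C8 do for Gpd1, while the groups do not overlap for Emc2 and Sidt1.

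The fourth comparison used gene lists for the cell types of spleen and for general programmes. Among the list means, that of erythroid genes, which are active in red cell precursors, had the widest range, and it varied within both groups. The mean log2 CPM of the erythroid list, which holds haemoglobins and genes of maturing red cells, ranged from 4.80 in C1 to 9.81 in C5, a 32.2-fold range. In C its mean was 7.16 ± 1.96 and in M 6.51 ± 1.72 (SD, n = 8 each), a difference of -0.65 (exact permutation p = 0.488). The first principal component held 50.2% of the variance and did not separate the groups (exact permutation p = 0.484). The cell cycle list followed the erythroid list across the 16 libraries, with Pearson's r of 0.978 and Spearman's rho of 0.900 (permutation p = 1e-05 for each, the smallest that the resamples can give, and 3e-05 adjusted over 3 relations). It held within C (r = 0.994), within M (r = 0.959) and without the 2 libraries farthest from the erythroid median (r = 0.964). T cell genes went the opposite way, with r of -0.820 and rho of -0.818 (permutation p = 0.00014, adjusted 0.00021), -0.819 within C, -0.838 within M and -0.759 without the 2 farthest libraries. Macrophage genes showed no such relation (r = 0.147, rho = 0.150, permutation p = 0.584 and 0.579, the same after adjustment; r = 0.168 without the 2 farthest libraries, -0.219 within C and 0.512 within M). Only these 3 lists were tested against the erythroid mean in this way, and others may vary with it too. From C1 to C5, the libraries of lowest and highest erythroid mean, the neutrophil mean rose from 1.54 to 3.04. The megakaryocyte mean rose from 4.56 to 5.73.

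**Figure D4:**
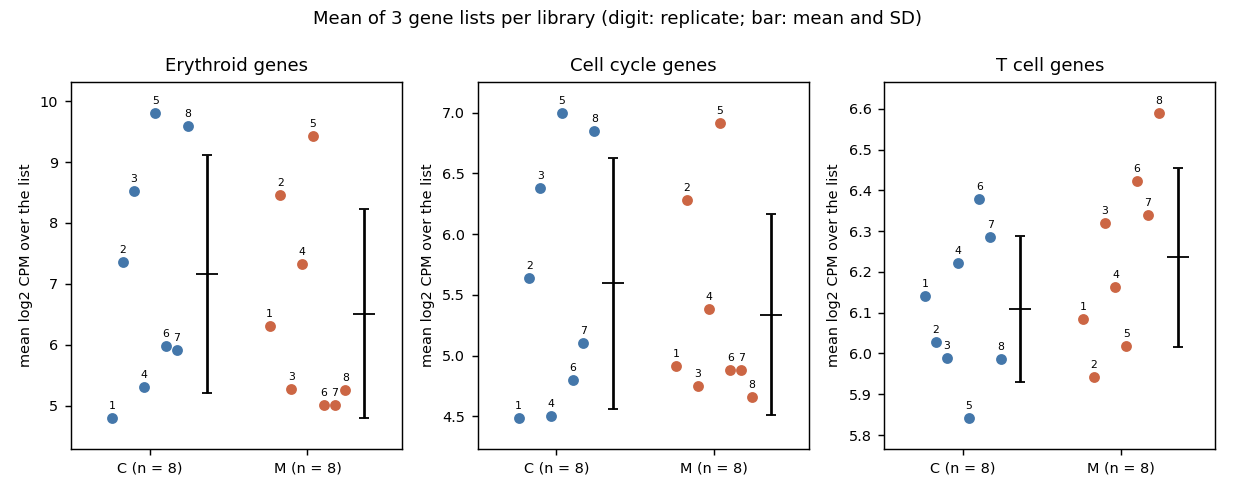
Mean log2 CPM of the erythroid, cell cycle and T cell lists in each library of C and M, with replicate numbers at the points and the mean and SD as bars. Libraries with high erythroid means, such as C5, C8 and M5, also have high cell cycle means, and the groups overlap in the erythroid panel, where C spans 4.80 to 9.81 and M spans 5.01 to 9.43.

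Camera with the preset correlation placed 15 of 37 lists past the threshold, 9 higher and 6 lower in M. None of the 15 calls held with an estimated correlation, where the adjusted p lay between 0.655 and 0.825, and fry and the exact permutation test of list means called 0 lists as well. T cell genes stood higher in M, 19 of 19 (median log2 fold change 0.13, camera adjusted p = 9.08e-05), among them Cd3e of the T cell receptor complex (0.11, SE 0.10) and its kinase Lck (0.13, SE 0.09). Cytotoxic and NK genes were higher in 17 of 19 (median 0.16, adjusted p = 0.00104), with Cd8a at 0.26 (SE 0.08). Th1 genes were higher in 7 of 8 (median 0.13, adjusted p = 0.00115), with the lineage factor Tbx21 at 0.26 (SE 0.10). Il12rb2, a chain of the interleukin 12 receptor, was the only member of that list past the threshold adjusted over the list alone, at 0.80 (SE 0.25, adjusted p = 0.0419). Over all genes its edgeR adjusted p was 0.601. Immediate early genes were higher in 16 of 20 (median 0.17, adjusted p = 0.00113), interferon-stimulated genes in 20 of 27 (0.13, 0.00354), smooth muscle genes in 9 of 12 (0.15, 0.00560), plasma cell genes in 12 of 14 (0.09, 0.0151) and B cell genes in 17 of 19 (0.05, 0.0312).

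On the lower side, heat shock genes were lower in 12 of 12 (median -0.22, camera adjusted p = 6.38e-05), among them the mitochondrial chaperones Hspd1 (-0.23, SE 0.10) and Hspe1 (-0.22, SE 0.08). The exact permutation p of this list's mean was 0.0435, the smallest among the 37 lists and 0.776 after adjustment. Ribosomal protein genes were lower in 39 of 45 (median -0.07, adjusted p = 2.35e-05), with Rpl7 at -0.23 (SE 0.06). Genes of oxidative phosphorylation were lower in 22 of 27 (-0.07, 9.08e-05), with Cox7c at -0.24 (SE 0.08), and genes of cholesterol synthesis in 16 of 18 (-0.07, 0.0107). Erythroid genes were lower in 30 of 30 (-0.73, 0.000722), and cell cycle genes in 28 of 28 (-0.35, 0.00995). No single member of these lists passed the threshold over all genes. With the erythroid mean as a covariate 10 of the 15 lists kept their call and direction. B cell, plasma cell and NF-κB component genes lost theirs (adjusted p of 0.643, 0.204 and 0.222), the erythroid list itself was at 0.820, and cell cycle genes then stood higher in M (0.0460). Megakaryocyte genes (8.69e-06) and glucocorticoid response genes (0.0398) then passed as well, both higher in M. Without M4, M7 and M8 together 9 lists were called, 7 of them among the 15, and megakaryocyte genes passed in that fit too. Without M3 9 lists were called, 8 of them among the 15.

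The fits with a library left out all used the preset correlation. They therefore cannot tell whether a kept call came from members that vary together. Among the lists named in the next sentence, the estimated correlation with all libraries ran from 0.137 (immediate early) to 0.80 (T cell). T cell, Th1, immediate early, heat shock, ribosomal protein and oxidative phosphorylation genes kept their camera call when any single library was left out. Smooth muscle genes lost theirs without M3 (adjusted p = 0.102), cytotoxic and NK genes without M3 (0.0803) or M8 (0.0625), and erythroid genes without C5 (0.194) or C8 (0.111). Interferon-stimulated genes lost theirs without C1 (0.0888), C4 (0.229), C6 (0.0610) or M3 (0.136), and cholesterol genes without C2 (0.0554), M1 (0.119), M2 (0.0871) or M5 (0.209). Plasma cell genes lost theirs without C3 (0.0784), C5 (0.133), C8 (0.0512), M3 (0.165) or M8 (0.0625). B cell genes lost theirs without C3 (0.126), C5 (0.682), C8 (0.297), M1 (0.169), M3 (0.0803), M4 (0.145) or M6 (0.103). Cell cycle genes lost theirs without C3 (0.123), C5 (0.577), C8 (0.433), M1 (0.0510), M3 (0.135), M6 (0.0574) or M8 (0.119).

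The remaining lists did not pass with the preset correlation and all 16 libraries. These were Th2 (camera adjusted p = 0.903), follicular helper and germinal centre (0.514), macrophage (0.139), monocyte and dendritic (0.954), neutrophil (0.20), mast, basophil and eosinophil (0.137), megakaryocyte (0.781), endothelial (0.659), fibroblast and matrix (0.864), mesothelial (0.139), pancreas (0.639) and adipocyte genes (0.509). The programmes were glucocorticoid response (0.109, 10 of 17 higher in M), circadian clock (0.579), hypoxia (0.692), cytokines and chemokines (0.639), MHC class II (0.514) and the unfolded protein response (0.514). Signs differed for 3 lists: endothelial genes had a median of 0.01 while their mean and camera pointed lower, monocyte and dendritic genes had a mean difference just above 0 while median and camera pointed lower, and MHC class II genes had a mean difference of -0.02 while median and camera pointed higher. Among cytokines and chemokines, 2 members passed the threshold adjusted over the list alone (adjusted p = 0.0220 each): Il18, a cytokine of the interleukin 1 family, at -0.40 (SE 0.10), and Tgfb2 at 0.39 (SE 0.11). Over all genes their edgeR adjusted p was 0.498 and 0.547.

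Of these lists, 5 passed with the preset correlation when a single library was left out. Macrophage genes did so without C7 (camera adjusted p = 0.00696), C8 (0.0140), M3 (0.0104) or M5 (0.0250), and neutrophil genes without C6 (0.0395), C7 (0.0145), M2 (0.0260) or M5 (0.0441), both lower in M. Mesothelial genes did so without C4 (0.0106), M6 (0.0318) or M7 (0.0365), higher in M. Mast, basophil and eosinophil genes passed without C6 (0.0190) or M2 (0.0435), lower in M, and glucocorticoid response genes passed without C2 (0.0479), higher in M. With an estimated correlation and all 16 libraries, the camera adjusted p of these 5 lists lay between 0.804 and 0.825.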

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

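The tests of the 45S-like genes, of DESeq2 without 3 libraries, of erythroid content and of estimated correlations were chosen after their results, or values close to them, had been seen, and the counts over other divisions of the libraries were set out before. Within each group of 8 libraries, a library was singled out when its gap to the nearest other, divided by the group's range, exceeded Dixon's 95% critical value. This happened for 5 of 164 groups of values, fewer than the 8 that chance would give at 1 in 20. M8 held 32473324 counts, against 20482588 in the next library of M. M4 had the highest mean log2 CPM of the pancreas list, 1.10 against 0.445. C3 had the lowest log2 CPM of Fer1l6, 0.27 against 1.38. C2 had the lowest log2 CPM of Asic1 among C libraries, 0.45 against 1.97. C1 had the highest log2 CPM of Ikbkb, 6.93 against 6.81.

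Counts of LOC108352829, which the GRCr8 gene table names Rn45sl2, a 45S pre-ribosomal RNA-like gene, were far higher in 3 libraries of M than in the rest. They were 1793 CPM in M4, 759 CPM in M7 and 5429 CPM in M8, against a median of 3.70 CPM in the other 13 libraries, and the related LOC108351097 (Rn45sl1) followed. The greater depth of M8 is argued against, since M7, with 16962712 counts in total, lay 205-fold above that median in CPM. A rise of such a size throughout group M is argued against, since 5 of 8 M libraries lay within 2 times the highest C library. That bound cannot decide on a small rise throughout M. Without M4, M7 and M8 the DESeq2 log2 fold change of LOC108352829 was 0.616 (DESeq2 adjusted p = 0.941). Incomplete removal of ribosomal RNA, genomic DNA and a response of some animals stay open and were not tested.

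DESeq2 called 34 genes where edgeR called 0, and 3 of 40 divisions of the libraries into 8 and 8, the real one included, gave as many, so chance could not be excluded (highest other 2784). Libraries M4, M7 and M8 may account for part of the 34: without them the log2 fold change of 10 genes halved or turned, all 10 higher in M, among them Ptger1 (3.50 to -0.09) and Serinc4 (2.87 to 0.06). For the other 24 genes, such as Asic1 (-1.71 to -2.03) and Gpd1 (-1.07 to -1.04), the log2 fold change did not halve or turn. With 10 of 34, a share between the bounds set for either answer, these libraries as the cause of the count cannot be told apart from other causes. Biological explanations of these genes stay untested.

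For 15 lists called by camera with the preset correlation, 41 of 100 divisions of the libraries, the real one included, called as many (highest other 22), so chance could not be excluded. The median estimated correlation between members of the called lists was 0.533, far above the preset 0.01, and a test that takes members as nearly independent may call lists that only vary together. With the erythroid mean as a covariate 10 of the 15 lists kept their call and direction. That fit used the preset correlation too, with which the other divisions, fitted without a covariate, called a median of 13 lists. It therefore cannot decide whether erythroid content was the whole cause. For B cell, plasma cell, NF-κB component and cell cycle genes, which lost or turned their call, erythroid content as the cause stays open. Their means had an absolute correlation of at least 0.696 with the erythroid mean. However, T cell and oxidative phosphorylation genes, which kept their call, had r of -0.820 and 0.819. An effect of prenatal stress on these lists stays open.

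The 1003 genes at an unadjusted p under 0.05 were equalled or exceeded in 23 of 100 divisions, the real one included, so chance could not be excluded (median of the others 472, highest 4586). For the 0 genes called by edgeR the comparison decides nothing, since each of the 100 divisions gives at least 0, and the highest other division gave 2057. Counts so far above the real ones point to a structure among the libraries that is not the division into M and C.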

How the results depend on the processing

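The fits with Eif2s3y, with the erythroid mean and Eif2s3y together, without M4, M7 and M8, and the permutation test of list means were chosen after seeing the data. The count of 0 genes held under every alternative except DESeq2 (34), counts summed over the first title number (2, Fbxl2 and LOC100362565), and single libraries left out (0 to 2). M4, M7 and M8 carry the title numbers 9, 24 and 48, so every summed M sample included a library with many 45S-like counts. Fbxl2 had 235, 124 and 180 counts in M4, M7 and M8 and at most 20 in any other library. Without these libraries its DESeq2 log2 fold change fell from 2.41 to 0.345, so its call with summed counts rested on them. Lists called, 15 of 37, ranged from 9 to 18 with single libraries left out and were 9 without M4, M7 and M8, and 0 with an estimated correlation, fry or permutation. The adjusted p of NF-κB components rose to 0.0877 without a filter, 0.392 with summed counts, 0.184 with a surrogate variable, 0.222 with the erythroid mean, 0.248 with Eif2s3y added, 0.288 without M4, M7 and M8, 0.804 with an estimated correlation, 0.736 with fry and 0.776 by permutation, and ranged from 0.00297 to 0.236 with single libraries left out. Treg genes reached 0.0381 with the stricter filter and 0.0388 with the title number as a block but 0.109 with counts summed over that number, and ranged from 0.0145 to 0.385 with single libraries left out. PI3K/Akt genes reached 0.0442 with library totals only. Th17 genes pointed lower with a surrogate variable (0.983), the erythroid mean (0.898) and both covariates (0.898). Cell cycle genes turned higher with a surrogate variable (0.184), the erythroid mean (0.0460) and both covariates (0.0462), and erythroid genes with their own mean (0.820) and both covariates (0.831). The change of erythroid genes follows from removing the list's own mean. Erythroid content as the cause of the changes of NF-κB component and cell cycle genes with the erythroid mean was tested and stays open. For the other changes the cause was not tested.

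Over all alternatives, the 20 genes of smallest p kept direction and side of the threshold in 619 of 640 cases and passed it in 21. The 22 fixed genes kept both in 680 of 702 and changed sign without passing in 22. The 32 other lists kept both in 792 of 991, lost a call in 98, gained one in 25, changed sign without a call in 71 and turned in 5. The number of genes at an unadjusted p under 0.05 ranged from 361 with the title number as a block to 1711 without a filter. The Th17 minus Treg score kept its direction throughout, with differences from -0.35 with lineage genes only (exact permutation p = 0.415), over -0.20 with 1 mean per first title number (0.400), to -0.00485 without M4, M7 and M8 (0.984). FPKM alternatives and Xist as a covariate were not run. The pancreas list had too few members under the stricter filter. Depth limits Il17a, Il17f and Il22, whose sums over a group were 0 to 4 counts.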

Other observations

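The tests of title numbers and of the neighbours of Asic1 were chosen after related values had been seen. Asb15, LOC103694306 and Slpi, chosen after their values were seen, and Pak2 each had 2 separate levels among the libraries. Asb15 was at 4.23 to 11.1 CPM in 7 libraries of C and at 0.302 CPM in C2, while in M it was at 6.33 CPM in M6 and at 0.485 CPM or less in the other 7. Its edgeR adjusted p was 0.610 with all libraries and 0.00872 without M6. LOC103694306 was at 0.166 to 0.722 CPM in C and at 2.02 to 4.65 CPM in M1, M2, M3, M4, M7 and M8, but at 0.627 CPM in M5 and 0.395 CPM in M6 (adjusted p = 0.162). Pak2 was at 2.64 to 4.98 CPM in M, and in C it was at 3.10 to 4.83 CPM in C1, C2 and C5 and at 13.9 to 25.2 CPM in the other 5 libraries. Slpi, a secreted inhibitor of leukocyte proteases, was at 142 CPM in M2, 170 CPM in M4 and 180 CPM in M7, and at 6.27 to 16.4 CPM in the other 13 libraries (adjusted p = 0.547).

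Asic1 and Gpd1, both lower in M by value, lie near each other in the GRCr8 gene table, with Smarcd1 between them. A candidate explanation was a change of the whole stretch of chromosome, such as a difference in copy number. It is argued against, since 0 of the 5 nearest tested genes had a log2 fold change under -0.5: Smarcd1 was at 0.02 (SE 0.05), Cox14 at -0.02 (SE 0.06), Cers5 at 0.07 (SE 0.09), Lima1 at 0.03 (SE 0.08) and Racgap1, a cell cycle gene, at -0.27 (SE 0.53). A variant or a regulatory change that acts on both genes stays open and was not tested.

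The first number in the library titles (4 numbers in C, 3 in M, none shared) may mark a litter or a day, which is a hypothesis only. Libraries with the same number had a mean correlation of log2 CPM of 0.977 over 13 pairs, against 0.967 over 43 pairs of the same group with different numbers (permutation of numbers within groups, p = 0.0390). Genes induced by glucocorticoids were looked at, since Tsc22d3 was at 280 CPM for number 48 and 101 CPM for number 17. Permuting the numbers within groups gave their list a p of 0.211 (0.326 adjusted over 37 lists, and 0.205 without number 48). Of the 37 lists, 10 had an unadjusted permutation p under 0.05, against 1.85 by chance, and 0 passed after adjustment. They included ribosomal proteins (76.6% of the variance within groups lay between numbers, permutation p = 0.00167, adjusted 0.0618), Th17 (70.6%, p = 0.0260, adjusted 0.120) and Treg genes (65.8%, p = 0.0408, adjusted 0.151). Part of the variance lies between numbers by chance alone: for PI3K/Akt genes, with a permutation p of 0.460, the share was still 35.9%. Erythroid (permutation p = 0.0239), cell cycle (0.0118) and oxidative phosphorylation genes (0.0337) were among the 10 too. Cell cycle and oxidative phosphorylation means followed the erythroid mean (r = 0.978 and 0.819), so the 10 lists are not independent. After regression on the erythroid mean the permutation p of glucocorticoid genes was 0.0214, or 0.345 adjusted over 36 lists. For Th17 genes it was then 0.922 and for Treg genes 0.0512, and 1 list, ribosomal proteins, passed after adjustment (0.0302). Whether the number matters for glucocorticoid genes cannot be told apart from chance with 7 numbers that are nested in the groups.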
